A study of Mus musculus with 16 samples.

How the data were processed

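The 16 libraries were RPF and total RNA libraries from the same 8 cultures, made with a commercial ribosome profiling kit, per the labels' protocols. The deposited values are a signal, namely read counts divided by a size factor per library, computed with DESeq2 by the authors, per the submitters' processing notes. Those notes list bcl2fastq 2.17, cutadapt 1.9.1, Bowtie2 2.2.8, TopHat2 2.1.0, HTSeq 0.6.1 and DESeq2 with the builds mm10 and GRCm38.p4. How strand, multi-mapping reads or footprint lengths were treated is not given in the sources used here. The values behaved as whole counts divided by one number per library: multiplying by that number gave whole reads within a tolerance of 0.001 for 100% of values, and the implied factors equalled median-of-ratios factors computed separately within RPF and within total RNA. Scaling within each assay sets the median gene of each library to the same level, so that a change shared by most genes would not appear, in TE either.

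The table held 21977 gene names, of which 27 looked like dates after spreadsheet conversion and 2 were repeated; none was blank, and all 16 value columns matched a sample. A RefSeq table of the assembly GRCm38.p6, not the build named in the notes, gave a chromosome for 21281 names (96.8%) and was used only for chromosome names and the order of neighbouring genes. Library depth, as recovered reads, was 17.5 to 23.8 M for RPF and 13.2 to 42.6 M for total RNA. A count of 0 in the shallowest library allows up to 3 reads, or 4.90 normalised reads, counting error only.

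Groups were taken from the labels. Each assay was fitted with limma 3.58.1 (R 4.3.3; trend in eBayes) on log2(value + 1) over its 8 libraries, with 3 genotype means and genes with a mean of at least 10. TE was tested as the interaction of assay and genotype over all 16 libraries. Calls are two-sided with a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The design, most alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. Named genes are Eif4g2, Map3k3, Sos1 and the Y-linked list. They further include the 6 highest and 6 lowest fold changes per assay among called genes with a mean of at least 50 and groups that do not overlap for Nat1-/- against Nat1+/-, and 4 and 4 for the comparisons with WT, predicted genes passed over. Up to 4 members of each list with the smallest adjusted p were added, and the 3 smallest p per direction where nothing was called. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists), for 3 or more tested members. Of the 68 list calls, 0 held when the correlation between genes was estimated from the data, so each list call stands beside that second p. Where a single value was compared, an exact permutation test was used.

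Alternatives included other filters, pseudocounts of 0.5 and 5, recomputed factors, equal library sums, other variance settings, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, leaving out each culture, and blocks. The RPF and total RNA library of one culture deviated together from their genotype means (r = 0.384 to 0.821 across genes, 8 of 8 matched best). The fit with a culture term is therefore paired and its TE results are given where they differ. Data were simulated from gene means over all 8 cultures, with 200 genes changed in Nat1-/-, and Nat1-/- was compared with Nat1+/-. The RPF fit (12871 genes) recovered 4.48% of changes of 1.5-fold, 43.3% of 2-fold and 87.7% of 4-fold, with 5 false calls. The total RNA fit (12899 genes) recovered 10.4%, 50.7% and 89.4% with 9 false calls. The TE fit (12827 genes) recovered 0%, 0% and 24.6% with 0, or 32.3% of 4-fold changes with the culture term. Far more genes than the 200 changed here were called in the real RPF and total RNA data. The TE simulation also added a culture spread to dispersions that already held it. These recovery rates therefore may not carry over to the data. A simulated raised list was called and 0 of 24 unchanged lists were. Genes were simulated independently of one another, so this could not show false list calls that arise from correlation between genes. Transcript lengths and untranslated regions were not used here, so no test of those features was made.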

Results

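Ribosome-protected fragments (RPFs, the mRNA pieces covered by translating ribosomes) and total RNA were sequenced from 8 cultures of RF8 mouse embryonic stem cells grown with LIF on gelatin, 16 libraries in all. The cultures comprised 2 of the wild-type (WT) line (WTex1 and WTex2, replicates 1 and 2), 3 Nat1+/- cultures (A7, B4 and C1, replicates 1, 2 and 3) and 3 Nat1-/- cultures (B12, B2 and C3, replicates 1, 2 and 3). Nat1 is the older name of Eif4g2 (also DAP5 or p97), a relative of the initiation scaffold eIF4G that lacks the binding site for the cap-binding protein eIF4E. The targeted cultures are named as separate clones and the WT replicates as cultures of one line, so the spread among WT replicates covers culture and handling but no clonal difference.

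RPF libraries held 17.5 to 23.8 M reads (M, mega-reads). Total RNA libraries fell into 2 depth classes, with 42.6 and 33.6 M reads in WTex1 and WTex2 and 42.5 M in B12, against 13.2, 14.6 and 14.8 M in A7, B4 and C1 and 16.4 and 14.2 M in B2 and C3. Depth therefore partly coincided with genotype, since both WT cultures were deep and the 3 Nat1+/- cultures shallow. Replicates of one genotype differed by more than sampling noise (chi-square per degree of freedom 19.4 to 120 for RPF and 13.1 to 101 for total RNA). Their log2 values correlated across genes at r = 0.966 to 0.987 for RPF and 0.970 to 0.991 for total RNA, genes not being independent replicates. The first principal component carried 63.1% of the RPF variance and 65.5% of the total RNA variance and set the 3 Nat1-/- cultures apart from the other 5. On it the Nat1+/- culture B4 (-56.9 for RPF) lay beside WT (-66.4 and -61.8). The second component carried 18.8% and 17.5%. On it WTex1, WTex2, B12 and B2 had positive scores and A7, B4, C1 and C3 negative scores in both assays, a division that crosses the Nat1-/- genotype.

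Eif4g2, the targeted gene, had RPF values of 17666 and 13862 normalised reads in WT, 10261, 7608 and 7275 in Nat1+/- and 1089, 1114 and 922 in Nat1-/- (replicates in order). The means were 15764 ± 2690 (SD, n = 2), 8381 ± 1636 (SD, n = 3) and 1042 ± 105 (SD, n = 3). Nat1-/- cultures thus kept 12.4% of the Nat1+/- footprints and 6.61% of the WT ones, and Nat1+/- cultures 53.2% of WT. Nat1-/- and Nat1+/- values did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; limma log2 fold change -2.99 ± 0.17 SE, adjusted p = 1.6e-05). Total RNA of Eif4g2 was 47932 and 26985 in WT, 15335, 12092 and 10674 in Nat1+/- and 12249, 8795 and 5085 in Nat1-/-. The Nat1-/- mean was 68.6% of the Nat1+/- mean with overlapping values (exact permutation p = 0.3). The RPF to total RNA ratio, taken here as translational efficiency (TE), changed by -2.38 ± 0.39 (log2, SE) between Nat1-/- and Nat1+/- (adjusted p = 0.0155). That TE call was lost without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 2.

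**Figure D1:**
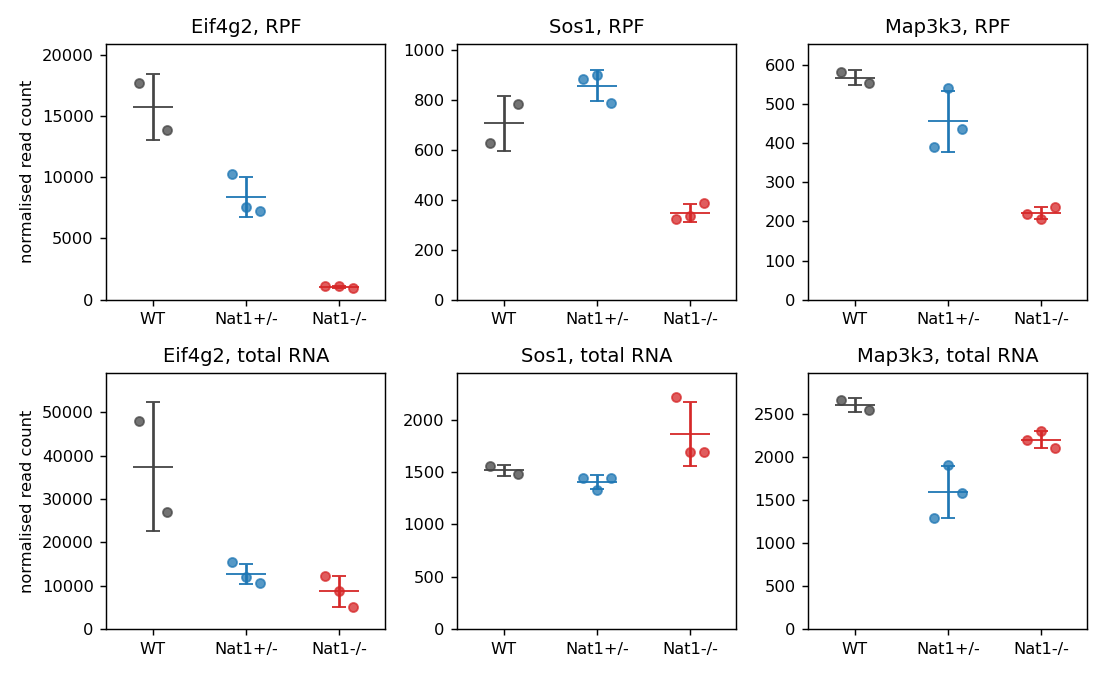
Normalised read counts of Eif4g2, Sos1 and Map3k3 in RPF (top) and total RNA (bottom) libraries; points are cultures, and bars give the mean and SD (n = 2 WT, 3 Nat1+/-, 3 Nat1-/-). Nat1-/- RPF values of Eif4g2 lie between 922 and 1114, below the Nat1+/- range of 7275 to 10261.

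The comparison of Nat1-/- with Nat1+/- asks what the loss of the remaining Nat1 allele changes, among targeted clones on both sides. Footprints of Islr2, a leucine-rich repeat membrane protein, rose by 5.05 ± 0.47 (log2, SE, n = 3 and 3; limma adjusted p = 1.0e-04), and those of the transcription factors Vax2 and Tbx20 by 4.60 ± 0.34 and 3.76 ± 0.44. Footprints of Peg3, a paternally expressed imprinted zinc finger gene, were 64.0-fold lower (adjusted p = 8.4e-06). Those of Dtna, a dystrobrevin, changed by -5.93 ± 0.35 and of the BMP receptor Bmpr1b by -5.50 ± 0.50 (log2, SE). The same genes moved in total RNA, with 5.25 ± 0.56 for Islr2, -6.83 ± 0.71 for Peg3 and -6.47 ± 0.36 for Dtna. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. Sos1, the guanine nucleotide exchange factor of RAS, and Map3k3, the kinase MEKK3, fell in RPF by 1.30 ± 0.15 and 1.03 ± 0.16 (log2, SE; adjusted p = 3.1e-04 and 0.0016). Their total RNA rose by 0.40 ± 0.14 and 0.49 ± 0.15 (adjusted p = 0.0422 and 0.0256). The total RNA call of Sos1 was lost without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 1 or 2. That of Map3k3 was lost without Nat1+/- replicate 1 or 3 or Nat1-/- replicate 2.

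Among the other genes with the widest RPF changes, Ldhal6b (4.16) rose and Crispld1 (-5.70), Aff3 (-5.57) and Piwil4 (-5.49) fell (log2). Psg29, a pregnancy-specific glycoprotein gene with near-identical relatives whose reads counting can split, read 6.07 ± 1.62. That call was lost without Nat1+/- replicate 3 or Nat1-/- replicate 2. In total RNA Tbx20 (4.53), Skida1 (4.36), Vax2 (4.28) and Foxd3 (3.94) rose and Xlr3a (-6.27), Plac8 (-5.97), Crispld1 (-5.84) and Snrpn (-5.78) fell. Of 13110 genes tested in RPF, 4737 passed an adjusted p of 0.05 (2303 higher and 2434 lower), as did 5519 of 13813 in total RNA (2730 higher and 2789 lower). With equal sums the splits were 1755 higher and 2738 lower and 2512 and 2903, and with a mean of at least 50 they were 2124 and 1729 and 2571 and 2065. Values of the 2 groups did not overlap for 48.1% and 50.2% of tested genes, against 10% by chance for 3 against 3. Of the genes tested in both, 1566 of the 2294 with more footprints also had more RNA (475.9 for independent lists) and 1863 of the 2393 with fewer footprints had less (480.5). Fold changes correlated across genes at r = 0.908, in libraries of the same cultures. Recovered whole reads (100% of values) gave 4622 RPF and 5396 total RNA calls with edgeR. Among the 5 cultures with shallow total RNA libraries, 3637 RPF and 4174 total RNA genes were called. Without Nat1-/- replicate 2 the RPF and total RNA counts were 2821 and 3608.

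Of 21 naive pluripotency genes, 12 rose and 3 fell in total RNA and 9 rose and 2 fell in RPF. Klf4 (2.51), Tbx3 (2.65) and Klf5 (1.33) had more RNA, while Dppa3, a germline and naive-state chromatin factor, changed by -4.87 ± 0.38 and Klf2 footprints by -1.01 ± 0.14. The list as a set was called in total RNA (camera adjusted p = 0.0118, adjusted p = 0.755 with an estimated correlation) and not in RPF (camera adjusted p = 0.0669). Of 13 general pluripotency genes, 6 rose in total RNA, among them Sox2 (0.78), Fgf4 (0.88), Sall4 (0.92) and Trim71 (1.22) (camera adjusted p = 0.0148, adjusted p = 0.731 with an estimated correlation). In RPF 3 rose, namely Fgf4 (0.69), Tdgf1 (0.81) and Pou5f1 (0.78) (camera adjusted p = 0.0310, adjusted p = 0.644 with an estimated correlation). No member of that list fell in either assay. Median total RNA deviations of the general list were 0.55, 0.44 and -0.10 in B12, B2 and C3 and -0.05, -0.42 and -0.14 in A7, B4 and C1, C3 lying among the latter. Leaving out 1 culture ended the camera call (adjusted p) of general pluripotency in RPF (0.0813 without Nat1+/- replicate 2 and 0.0621 without Nat1-/- replicate 2). With 1 culture left out camera also called naive pluripotency in RPF (without Nat1+/- replicate 1 or 3 or Nat1-/- replicate 1). A called median moved over 1.5 times for general pluripotency in RPF (0.30 to 0.52 without Nat1-/- replicate 3) and general pluripotency in total RNA (0.63 to 0.41 without Nat1+/- replicate 2).

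Lineage lists mostly held more genes that fell than rose. Over all tested genes, calls of at least 2-fold also leaned downward (794 higher and 1673 lower in RPF, 930 and 1765 in total RNA). The lists were not compared with genes of like expression, so the lean is not shown to be particular to lineage genes. Of 8 neuroectoderm genes tested in total RNA, 2 rose and 6 fell, with Sox11 (-3.69), Gap43 (-2.69) and Map2 (-2.06) among the lower and Sox1 at 2.18 ± 0.25 (camera adjusted p = 0.0474, adjusted p = 0.731 with an estimated correlation). In RPF 2 rose and 5 fell of 9 (camera adjusted p = 0.0652). Of 14 formative and primed epiblast genes, 3 rose and 5 fell in RPF, including Sox4 (-3.33), Dnmt3a (-2.24) and Sall2 (-2.31), and 4 rose and 5 fell in total RNA (camera adjusted p = 0.0980 and 0.485). In RPF, 5 of 15 primitive endoderm and endoderm genes fell and 1 rose, with Lamb1 (-2.87) and Dab2 (-3.59) against Sox7 (2.70) (camera adjusted p = 0.0908). Trophoblast genes divided, with Tfap2c (-2.19), Plet1 (-2.18) and Ascl2 (-2.23) lower and 3 higher, Tead4 (1.09) among them, of 11 (camera adjusted p = 0.479). Of 10 mesendoderm and mesoderm genes 2 fell in RPF, Pdgfrb (-1.85) and Wnt3 (-2.83) (camera adjusted p = 0.458). The call of Wnt3 was lost without Nat1+/- replicate 2 or 3 or Nat1-/- replicate 1 or 2. Fibroblast markers had a median RPF change of -1.43 in this comparison (camera adjusted p = 0.0667). The camera call was lost (adjusted p) by neuroectoderm in total RNA (0.0527 without Nat1-/- replicate 1). Not called in the main fit but called by camera with 1 culture left out were formative genes in RPF (without Nat1+/- replicate 1), endoderm in RPF (without Nat1+/- replicate 1) and neuroectoderm in RPF (without Nat1+/- replicate 3 or Nat1-/- replicate 1). Set calls gained when 1 culture was left out were those of endoderm in total RNA (without Nat1+/- replicate 1).

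In total RNA 11 of 18 imprinted genes fell and 2 rose (camera adjusted p = 0.0065, adjusted p = 0.731 with an estimated correlation), with Snrpn (-5.78), Zim1 (-3.61) and Ndn (-1.30) beside Peg3 (-6.83). In RPF 8 fell and Nnat alone rose (1.24 ± 0.24; camera adjusted p = 0.0166, adjusted p = 0.644 with an estimated correlation). Of 18 germline genes, 1 rose and 12 fell in RPF (camera adjusted p = 3.2e-04, adjusted p = 0.644 with an estimated correlation), led by the X-linked homeobox genes Rhox5 (-5.10), Rhox6 (-4.40) and Rhox9 (-3.90), members of a cluster of similar genes. In total RNA 1 rose and 12 fell of 16 (camera adjusted p = 9.9e-04, adjusted p = 0.731 with an estimated correlation), including Ddx4 (-1.76). Only 2 genes of the 2-cell-like list reached the minimum value, in total RNA alone, and both fell (Zscan4d (-3.59) and Sp110 (-2.18)), Sp110 losing its call without Nat1+/- replicate 2 or Nat1-/- replicate 2. Of 62 replication-dependent histone genes, 1 rose and 36 fell in total RNA (camera adjusted p = 1.8e-08, adjusted p = 0.731 with an estimated correlation), Hist1h3i (-1.43) and Hist1h2ak (-0.98) among them. RPF had 4 up and 8 down (camera adjusted p = 0.458). Histone genes are near-identical copies whose reads counting can divide among them. No longer called as sets with 1 culture left out (adjusted p) were imprinted genes in RPF (0.0609 without Nat1+/- replicate 2). Camera further called, with 1 culture left out, histones in RPF (without Nat1-/- replicate 1). Over 1.5 times was also the move of the called median for germline genes in total RNA (-1.57 to -0.99 without Nat1+/- replicate 2).

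Signalling lists went both ways. Of 33 genes of the receptor, RAS and MAPK cascade, 5 rose and 8 fell in RPF and 9 rose and 4 fell in total RNA (camera adjusted p = 0.172 and 0.172). In RPF the FGF receptor Fgfr2 read -4.57 ± 0.40, Fgfr1 -1.12 ± 0.14 and Nras 0.83 ± 0.13. ERK response genes counted 3 up and 4 down of 18 in RPF (camera adjusted p = 0.962). The phosphatases Dusp4 (-3.74) and Dusp5 (-1.29) and the early gene Egr1 (-2.92) fell and Etv5 rose (0.82). In the WNT response list 5 of 9 fell in RPF, including Nkd1 (-2.21), Sp5 (-1.63) and Axin2 (-0.70), and Notum rose (2.02; camera adjusted p = 0.458). Axin2 lost its call without Nat1+/- replicate 1 or Nat1-/- replicate 2, and Sp5 without Nat1+/- replicate 2 or 3 or Nat1-/- replicate 2. Of 10 retinoic acid response genes Crabp1 (-2.47) fell and Meis2 rose (3.24; camera adjusted p = 0.519). The ATF4 and integrated stress response list held 6 higher and 7 lower genes of 24 (camera adjusted p = 0.780), with Atf4 (0.93), Ppp1r15a (1.95) and Mthfd2 (0.87) up and the serine synthesis enzyme Phgdh (-2.63) down. Of 16 p53 targets 6 fell in RPF and 0 rose (camera adjusted p = 0.0216, adjusted p = 0.644 with an estimated correlation), among them Ccng1 (-1.20), Bbc3 (-0.90) and Fas (-4.05). In total RNA 1 rose and 6 fell (camera adjusted p = 0.166). Set calls lost with 1 culture left out (adjusted p) were those of p53 targets in RPF (0.0629 without Nat1+/- replicate 3 and 0.0840 without Nat1-/- replicate 3).

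Of 81 cytosolic ribosomal protein genes, 34 rose and 0 fell in RPF (camera adjusted p = 3.5e-09, adjusted p = 0.644 with an estimated correlation), including Rpl22l1 (1.52), Rpl30 (1.02), Rpl14 (1.01) and Fau (1.06). In total RNA 1 rose and 9 fell (camera adjusted p = 0.0768). The median RPF deviation of these genes from the mean of the 8 cultures was 0.80 in B12, 0.26 in B2 and -0.38 in C3, against -0.38, -0.54 and -0.39 in A7, B4 and C1 and 0.38 and 0.23 in WT. C3 thus lay beside the Nat1+/- cultures, narrowly above all 3. The nuclear-encoded respiratory chain had 28 higher and 1 lower of 77 genes in RPF (camera adjusted p = 5.2e-05, adjusted p = 0.644 with an estimated correlation), such as Cox6c (0.65) and Ndufb11 (0.59). In total RNA 4 rose and 3 fell (camera adjusted p = 0.674). Among 29 eIF1, eIF2, eIF3 and eIF5 factors 9 rose and 0 fell in RPF (camera adjusted p = 0.0751), with Eif1 (1.33), Eif3f (0.80) and Eif6 (0.71). The calls of Eif3f and Eif6 were lost without Nat1+/- replicate 2 or Nat1-/- replicate 2. In total RNA 2 rose and 7 fell, Eif3a (-0.83) and Eif3m (-0.57) among the lower (camera adjusted p = 0.209). In the eIF4G family and cap-binding list 2 rose and 2 fell of 18 in RPF (camera adjusted p = 0.696). The eIF4G relative Eif4g3 changed by -2.04 ± 0.15 and -1.52 ± 0.16 in RPF and total RNA. None of the mitochondrially encoded mRNAs passed in either assay (8 and 11 tested, limma, 0 calls; the smallest adjusted p in RPF was that of mt-Nd2, 0.275, and in total RNA that of mt-Atp6, 0.117). With 1 culture left out camera also called eIF1, eIF2, eIF3 and eIF5 factors in RPF (without Nat1-/- replicate 3), ribosomal proteins in total RNA (without Nat1+/- replicate 2 or Nat1-/- replicate 2) and mitochondrially encoded mRNAs in total RNA (without Nat1-/- replicate 3). The called median changed over 1.5 times for ribosomal proteins in RPF (0.68 to 0.38 without Nat1-/- replicate 1).

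Fibroblast markers, which mark cells that could accompany stem cells, were high in WT. Col1a1 RPF values were 1911 and 5922 in WT, 77, 707 and 93.4 in Nat1+/- and 22.7, 45.3 and 38.7 in Nat1-/-. Acta2 read 928 and 2976 in WT, 26, 164 and 33.6 in Nat1+/- and 3.24, 16.9 and 6.83 in Nat1-/-. Among Nat1+/- cultures B4 was highest for both. Between Nat1-/- and Nat1+/- 1 rose and 5 fell of 11 in RPF (camera adjusted p = 0.0667) and 4 of 10 fell in total RNA (camera adjusted p = 0.0458, adjusted p = 0.731 with an estimated correlation). Y-linked genes were lower in B12 and B2 than in the other 6 cultures, C3 included (median total RNA deviations -0.91 and -1.16 against 0.37 in C3). Of these, Eif2s3y (-0.86 ± 0.17) and Kdm5d (-2.19 ± 0.76) passed in RPF and Eif2s3y (-1.13 ± 0.23) and Zfy1 (-3.59 ± 1.17) in total RNA. Kdm5d lost its RPF call without Nat1+/- replicate 2 or Nat1-/- replicate 1 or 2, and Zfy1 its total RNA call without Nat1+/- replicate 2 or Nat1-/- replicate 1 or 2. Among the Y-linked genes without a call, Ddx3y read -0.19 ± 0.35, Uty -0.67 ± 0.30, Zfy1 -2.23 ± 1.32 and Uba1y -1.78 ± 0.65 in RPF, and Usp9y read -0.36 ± 0.79 in total RNA. Leaving out 1 culture ended the camera call (adjusted p) of fibroblast markers in total RNA (0.0646 without Nat1+/- replicate 2 and 0.0836 without Nat1-/- replicate 1). Uncalled in the main fit but called by camera with 1 culture left out were fibroblast markers in RPF (without Nat1+/- replicate 1 or 3 or Nat1-/- replicate 3), Y-linked genes in RPF (without Nat1+/- replicate 3 or Nat1-/- replicate 3) and Y-linked genes in total RNA (without Nat1-/- replicate 3).

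In the main fit, without pairing by culture, translational efficiency fell in Nat1-/- relative to Nat1+/- for a set of genes including the pair above. Sos1 TE changed by -1.70 ± 0.19 (log2, SE, n = 3 and 3; limma interaction adjusted p = 0.0018) and Map3k3 TE by -1.51 ± 0.21 (adjusted p = 0.0040). Crebbp, a histone acetyltransferase, read -1.83 ± 0.24, the adhesion receptor Adgrl1 -1.73 ± 0.21, the mRNA decay factor Patl1 -1.69 ± 0.31 and the kinase Wnk1 -1.68 ± 0.19. TE rose for Sorbs2 (2.87), Psg16 (1.26) and Rpl22l1 (1.17), and for Bcl2l2 (1.66), a further gene added after its value was seen. For Sorbs2 total RNA changed by -3.06 and footprints by -0.19, so its higher TE came from less RNA. In that fit 71 genes fell and 4 rose of 12933 tested. The 75 were all called again when the RPF and total RNA library of a culture shared a term, a fit that called 1275 (446 higher and 829 lower). The number of TE calls and their balance therefore depend on whether the libraries are paired. The paired fit called 14 genes for Nat1-/- against the 2 WT cultures. The first principal component of TE per culture (35.8% of the variance) was 29.4, 23.1 and 24.2 in A7, B4 and C1. It was -13.7 and 0.9 in WT and -36.5, -25.7 and -1.7 in B12, B2 and C3. Nat1+/- cultures thus stood apart in TE, and the 1275 calls cannot be read as a change of Nat1-/- alone.

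Of the 71 lower genes, 40 had called decreases in RPF and 52 called increases in total RNA, 21 having both. The median changes were -0.46 in RPF, 0.65 in total RNA and -1.15 in TE. Relative to the Nat1+/- mean the median TE of the 71 was -1.37 in B12, -1.23 in B2 and -0.92 in C3, the genes having been chosen on these cultures. Against WT the median TE change of the 71 was -0.74, and that of Nat1+/- against WT was 0.40. The RAS and MAPK cascade list had lower TE as a set (camera adjusted p = 1.4e-06, adjusted p = 0.0503 with an estimated correlation), with 2 of 33 genes called, Sos1 and Map3k3, and 8 adjusted over the list alone. The study chose both genes on these samples, so they are not independent evidence. Rasa1 read -0.59 ± 0.14, called only with the shared culture term (adjusted p = 0.0219). Of the 10 mRNAs reported as Nat1 dependent, 2 fell (3 adjusted over the list alone), the same pair, and the list was not called as a set (camera adjusted p = 0.163; RPF 3 up and 3 down). ERK response genes had lower TE as a set (camera adjusted p = 0.0370, adjusted p = 0.397 with an estimated correlation) with none called singly. Spred1 read -1.42 ± 0.33 (adjusted p = 0.0750, 0.0270 with the culture term). The ERK list median was -0.32 here, but 0.01 for Nat1-/- against WT and 0.26 for Nat1+/- against WT. A fall of ERK response TE below WT was thus not shown. The same medians were -0.27, -0.12 and 0.19 for the RAS and MAPK cascade and -0.19, 0.03 and 0.22 for naive pluripotency. With the culture term 8 genes of the RAS and MAPK cascade, 5 naive pluripotency genes, 3 formative genes and 2 each of the ERK, WNT, p53 and general pluripotency lists had called decreases. Higher and lower calls were 2 and 1 in the cap-binding list, 1 and 2 among imprinted genes, 1 and 1 in the ATF4 list and 0 and 1 in the mesendoderm and endoderm lists. The formative list was called only with the culture term (camera adjusted p = 0.0430, 0.286 without it). The camera call was lost (adjusted p) by ERK response in TE (0.0571 without Nat1+/- replicate 1).

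TE was higher as a set for ribosomal protein genes (median 0.83; camera adjusted p = 1.8e-36, adjusted p = 0.315 with an estimated correlation), with Rpl22l1 called over all genes and 57 of 81 adjusted over the list alone. It was higher likewise for the respiratory chain (median 0.31; camera adjusted p = 8.2e-11, adjusted p = 0.315 with an estimated correlation) and for eIF1, eIF2, eIF3 and eIF5 factors (median 0.39; camera adjusted p = 2.8e-08, adjusted p = 0.315 with an estimated correlation). Replication-dependent histones had higher TE too (median 0.54; camera adjusted p = 3.9e-12, adjusted p = 0.397 with an estimated correlation). With the culture term 17 ribosomal protein genes, 5 of these initiation factors, 3 respiratory chain genes and 3 histones had called increases, and 1 histone a decrease. Against WT the median TE changes of Nat1-/- were -0.10 for ribosomal proteins, 0.07 for the respiratory chain, 0.11 for these factors and 0.06 for histones. Camera called none of them with all cultures, so a rise over WT was not shown. The matching medians of Nat1+/- against WT were -0.90, -0.22, -0.29 and -0.49. The ribosomal protein median TE deviation was 0.82, 0.22 and -0.23 in B12, B2 and C3 and -0.61, -0.55 and -0.47 in A7, B4 and C1 (exact permutation p = 0.1, the smallest possible). The TE count changed with the cultures used. It was 10, 23 and 9 genes without Nat1+/- replicate 1, 2 or 3, 26, 6 and 376 without Nat1-/- replicate 1, 2 or 3, and 6 among the cultures with shallow total RNA libraries. Map3k3 lost its TE call without Nat1+/- replicate 3 or Nat1-/- replicate 2 and Crebbp without Nat1-/- replicate 2. Patl1 lost it without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 1 or 2 and Rpl22l1 without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 1 or 2. Sorbs2 lost it without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 2 and Psg16 without Nat1+/- replicate 1, 2 or 3 or Nat1-/- replicate 2. Sos1, Adgrl1 and Wnk1 kept their calls in all 6 of these fits. Moves of a called median over 1.5 times were those of ribosomal proteins in TE (0.83 to 0.53 without Nat1-/- replicate 1) and histones in TE (0.54 to 0.29 without Nat1-/- replicate 1). Histone TE deviations were 0.57, 0.03 and -0.0046 in B12, B2 and C3 and -0.37, -0.23 and -0.31 in A7, B4 and C1.

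**Figure D2:**
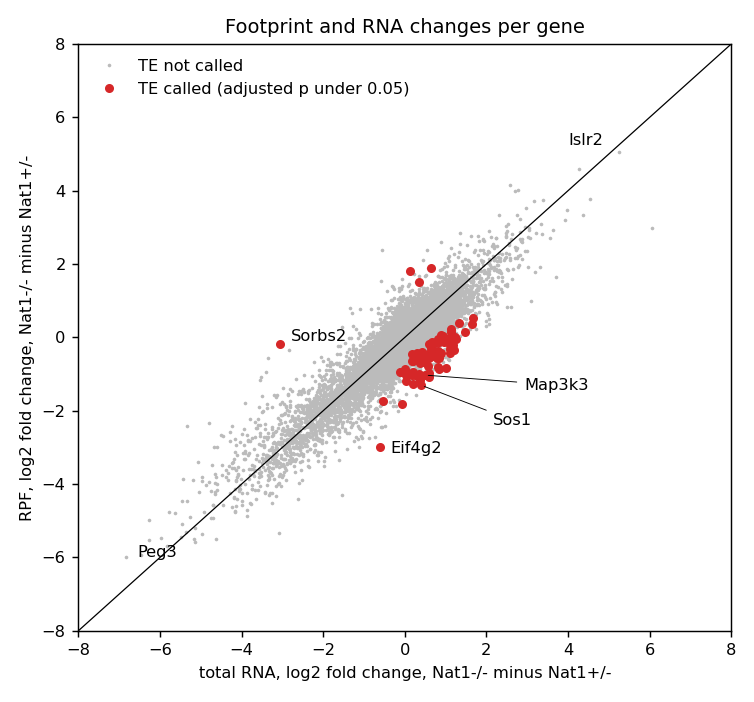
Log2 fold changes (Nat1-/- minus Nat1+/-) of 12933 genes in total RNA (x axis) and RPF (y axis); red points are the 75 genes with a TE adjusted p under 0.05, and the line marks equal changes. Fold changes correlate at r = 0.908 across genes, and 71 of the 75 red points lie below the line.

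Against WT, Nat1-/- cultures had more footprints of Nkx6-3, a homeobox gene (5.95 ± 0.70 log2, SE, n = 3 and 2; adjusted p = 3.0e-04), Islr2 (5.66 ± 0.52), Ppp1r14d (5.26 ± 0.34) and the histidine-degrading enzyme Hal (4.77 ± 0.51). They had fewer of the mesenchymal genes Col1a2 (-8.46 ± 0.90), Acta2 (-7.63 ± 0.84) and Tagln (-7.42 ± 0.66), genes of fibroblast type that were high in both WT cultures, and of Fndc3c1 (-7.44 ± 0.89). In total RNA Nkx6-3 (5.97), Islr2 (5.83), Vax2 (4.55) and Inhbb (4.53) rose and Acta2 (-9.29), Prss23 (-8.33), Gbp2b (-8.14) and Gbp2 (-8.04) fell; Gbp2b and Gbp2 belong to a family of similar interferon-induced genes. Sos1 and Map3k3 footprints changed by -1.02 ± 0.17 and -1.36 ± 0.18 (adjusted p = 0.0016 and 6.0e-04), and their total RNA read 0.29 ± 0.15 and -0.24 ± 0.17 without a call. The limma fit called 4567 RPF genes (2167 higher, 2400 lower) and 4839 total RNA genes (2231 higher, 2608 lower). With libraries scaled to equal sums, which shifts the median gene by -0.11 in RPF and -0.12 in total RNA, the splits were 1556 higher and 2740 lower and 1628 higher and 3129 lower. Recovered reads gave 4445 and 4925 calls with edgeR, the 3 cultures with deep total RNA libraries alone 4394 and 5297, and leaving out WT replicate 1 or 2 left 1866 or 2558 RPF and 2360 or 2651 total RNA calls.

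Naive pluripotency genes were mostly higher than in WT. In RPF 13 rose and 2 fell of 21 (camera adjusted p = 4.0e-04, adjusted p = 0.394 with an estimated correlation), including Tbx3 (4.17), Klf4 (2.78) and Dppa5a (2.07) up and Dppa3 (-5.21) down. Total RNA had 13 up and 2 down (camera adjusted p = 1.7e-04, adjusted p = 0.525 with an estimated correlation). Of 13 general pluripotency genes 4 rose in RPF, among them Fgf4 (1.30), Tdgf1 (1.44) and Sox2 (0.99) (camera adjusted p = 0.0589). Formative genes fell, 8 of 14 with 1 higher (camera adjusted p = 0.0017, adjusted p = 0.357 with an estimated correlation), Dnmt3a (-2.75), Sox4 (-3.46), Sall2 (-3.11) and Zic2 (-2.78) among them. Neuroectoderm genes fell likewise, 6 of 9 against 2 higher (camera adjusted p = 0.0066, adjusted p = 0.266 with an estimated correlation), with Sox11 (-4.83), Nes (-4.02) and Pax6 (-3.30). Of 10 mesendoderm genes 4 fell, including Wnt3 (-5.63) (camera adjusted p = 0.106). Of 11 trophoblast genes 8 fell and 2 rose, Krt18 (-3.57) and Krt7 (-3.11) lower (camera adjusted p = 0.0589). Fibroblast markers had median RPF deviations from the mean of the 8 cultures of 0.77 and 1.14 in WT, -0.31, 0.77 and 0.25 in A7, B4 and C1 and -1.01, -1.29 and -0.59 in B12, B2 and C3. Those of the formative list were 1.35 and 1.03, -0.36, 0.43 and -0.18, and -0.88, -0.50 and -1.11. Endoderm genes counted 4 up and 4 down of 15, Lamb1 (-2.41) and Dab2 (-4.29) among the latter (camera adjusted p = 0.509). Set calls gained when 1 culture was left out were those of trophoblast in RPF (without WT replicate 1 or Nat1-/- replicate 2 or 3) and general pluripotency in RPF (without WT replicate 2 or Nat1-/- replicate 3).

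Imprinted genes fell together relative to WT, 15 of 18 in RPF (camera adjusted p = 1.1e-06, adjusted p = 0.266 with an estimated correlation). So did 15 of 18 in total RNA (camera adjusted p = 2.0e-07, adjusted p = 0.382 with an estimated correlation), none rising in either. Footprints of Igf2, the fetal growth factor, changed by -6.54 ± 0.54, of Snrpn by -6.07 ± 0.51 and of Peg3 by -5.66 ± 0.29. Median RPF deviations of the imprinted list were 1.15 and 1.00 in WT and -0.22, 0.42 and 0.20 in A7, B4 and C1. They were -0.62, -0.83 and -0.75 in B12, B2 and C3. Fibroblast markers were likewise highest in WT and, among Nat1+/- cultures, in B4. Cell composition was not measured, so its part in this fall was not tested. Germline genes divided, 4 up and 5 down, with Hormad1 at 2.75 and Rhox5 at -5.12 (camera adjusted p = 0.725). Fibroblast markers fell in 7 of 11 (camera adjusted p = 6.8e-04, adjusted p = 0.357 with an estimated correlation). WNT response genes fell in 3 of 9 (camera adjusted p = 0.0204, adjusted p = 0.357 with an estimated correlation), namely Sp5 (-4.70), Axin2 (-1.05) and Nkd1 (-2.25). Axin2 lost its call without WT replicate 2 and Nkd1 without WT replicate 1 or 2. The respiratory chain had 15 higher and 1 lower of 77 (camera adjusted p = 6.3e-04, adjusted p = 0.556 with an estimated correlation), including Cox6c (0.92) and Cox8a (1.04). Histones had 1 higher and 7 lower of 60 (camera adjusted p = 0.0110, adjusted p = 0.736 with an estimated correlation). Other lists were not called as sets in RPF, among them ERK response (1 up, 4 down, Dusp4 at -4.13 and Egr1 at -3.33), RAS and MAPK cascade (4 up, 6 down, Fgfr2 at -5.16) and the cap-binding complex (2 up, 4 down). Nor were retinoic acid response (1 up, 5 down), ATF4 response (2 up, 7 down), p53 targets (1 up, 2 down), Nat1-dependent mRNAs (4 up, 2 down), Y-linked genes (0 up, 2 down) or ribosomal proteins (0 up, 1 down). In total RNA 8 lists were called as sets by camera (median log2 change; adjusted p), and 0 with an estimated correlation (lowest adjusted p = 0.382 with an estimated correlation). Medians above 0 belonged to naive pluripotency (1.02; 1.7e-04) and nuclear-encoded respiratory chain (0.22; 0.0040). Medians below 0 belonged to formative and primed epiblast (-1.90; 0.0020), neuroectoderm (-2.82; 0.010), WNT response (-0.97; 0.0291), imprinted genes (-1.98; 2.0e-07), fibroblast markers (-1.13; 0.0023) and replication-dependent histones (-0.38; 7.2e-04). No longer called as sets with 1 culture left out (adjusted p) were histones in RPF (0.267 without WT replicate 1 and 0.221 without Nat1-/- replicate 3), WNT response in RPF (0.0676 without Nat1-/- replicate 3) and respiratory chain in total RNA (0.199 without WT replicate 1). Set calls lost with 1 culture left out (adjusted p) were those of WNT response in total RNA (0.0648 without WT replicate 2 and 0.0629 without Nat1-/- replicate 3) and histones in total RNA (0.0765 without WT replicate 2). Camera further called, with 1 culture left out, mitochondrially encoded mRNAs in RPF (without WT replicate 2 or Nat1-/- replicate 1 or 2), ribosomal proteins in RPF (median -0.32 without Nat1-/- replicate 1 and 0.25 without Nat1-/- replicate 3) and ATF4 response in RPF (without Nat1-/- replicate 3). With 1 culture left out camera also called Y-linked genes in RPF (without Nat1-/- replicate 3), trophoblast in total RNA (without WT replicate 1) and ATF4 response in total RNA (without WT replicate 1 or Nat1-/- replicate 3). Lists not called in the main fit but called by camera with 1 culture left out were mitochondrially encoded mRNAs in total RNA (without Nat1-/- replicate 1), general pluripotency in total RNA (without Nat1-/- replicate 3) and Y-linked genes in total RNA (without Nat1-/- replicate 3). A called median moved over 1.5 times for histones in RPF (-0.33 to -0.55 without WT replicate 2 and -0.53 without Nat1-/- replicate 1), respiratory chain in RPF (0.29 to 0.19 without Nat1-/- replicate 1) and histones in total RNA (-0.38 to -0.60 without WT replicate 1 and -0.25 without Nat1-/- replicate 3). Over 1.5 times was also the move of the called median for respiratory chain in total RNA (0.22 to 0.35 without WT replicate 2). Histone RPF deviations were 0.44 and 0.02 in WT against 0.22, -0.01 and -0.50 in B12, B2 and C3, so that the histone call in RPF rested on WTex1 and C3.

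TE differed from WT for 1 gene, the kinase Mark3 (-1.11 ± 0.15; adjusted p = 0.0215, 0.0301 with the culture term), of 12933. The culture term gave 14 calls (4 higher, 10 lower), DESeq2 39 and edgeR 0 (326 genes at a raw p under 0.05). No gene was called without WT replicate 1 or 2 or Nat1-/- replicate 2 (184, 148 and 209 at a raw p under 0.05). Sos1 TE read -1.30 ± 0.21 and Map3k3 TE -1.11 ± 0.23 (adjusted p = 0.0719 and 0.304). A pair of lists were called as sets with lower TE, both containing that pair. They were the RAS and MAPK cascade (camera adjusted p = 0.0028, adjusted p = 0.137 with an estimated correlation) and the mRNAs reported as Nat1 dependent (camera adjusted p = 0.0121, adjusted p = 0.137 with an estimated correlation). With the culture term neither was called (camera adjusted p = 0.0671 and 0.104). Set calls gained when 1 culture was left out were those of respiratory chain in TE (median 0.24 without WT replicate 1, -0.10 without WT replicate 2, 0.11 without Nat1-/- replicate 2 and 0.13 without Nat1-/- replicate 3), histones in TE (median 0.45 without WT replicate 1, -0.38 without WT replicate 2, -0.18 without Nat1-/- replicate 1 and 0.17 without Nat1-/- replicate 3) and ribosomal proteins in TE (median -0.25 without WT replicate 2, -0.34 without Nat1-/- replicate 1 and 0.19 without Nat1-/- replicate 3). Camera further called, with 1 culture left out, eIF1, eIF2, eIF3 and eIF5 factors in TE (without Nat1-/- replicate 3) and mitochondrially encoded mRNAs in TE (without Nat1-/- replicate 3). The called median changed over 1.5 times for Nat1-dependent mRNAs in TE (-0.07 to -0.29 without WT replicate 1 and -0.13 without Nat1-/- replicate 2) and RAS and MAPK cascade in TE (-0.12 to -0.07 without WT replicate 2, -0.06 without Nat1-/- replicate 1 and -0.20 without Nat1-/- replicate 3).

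Nat1+/- cultures were compared with WT to see what accompanies loss of 1 allele and clonal derivation. Footprints of Hal (3.71 ± 0.51 log2, SE, n = 3 and 2; adjusted p = 0.0082) and of the meiotic cohesin Smc1b (3.37 ± 0.53) rose, as did those of Ftl1 (2.97) and Nkx6-3 (2.96). Igf2 (-5.10 ± 0.54; adjusted p = 0.0045), Psg29 (-8.20), Acta2 (-4.95) and Tagln (-4.52) fell, the last pair being among the fibroblast-type genes high in WT. In total RNA Smc1b (3.52), Hal (2.85), Slc6a7 (2.82) and Col13a1 (2.42) rose and Igf2 (-5.73), Acta2 (-4.80), Tagln (-4.44) and Col1a1 (-4.36) fell. Eif4g2 itself changed by -0.92 ± 0.19 in RPF and -1.52 ± 0.35 in total RNA (adjusted p = 0.0239 and 0.0277), Map3k3 total RNA by -0.73 ± 0.17, and Sos1 passed in neither assay (0.29 ± 0.17 and -0.11 ± 0.15). The limma fit called 1374 RPF genes (701 higher, 673 lower) and 1383 total RNA genes (636 higher, 747 lower; 452 and 1154 with libraries scaled to equal sums). These counts rested on the WT cultures. Without WT replicate 1 or 2, 0 or 23 RPF genes (1787 at a raw p under 0.05 for the former) and 0 and 0 total RNA genes (2006 and 2959) were called. Hence every gene called in this paragraph lost its call in at least 1 such fit. Without Nat1+/- replicate 1 or 3, 84 or 388 RPF and 186 or 573 total RNA genes were called. With all cultures edgeR called 1374 and 1490 and DESeq2 2519 and 2559. Every WT total RNA library was deep and every Nat1+/- one shallow, so no comparison within a depth class could be made. Reads thinned to equal depth left both counts within 1.5 times.

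Naive pluripotency genes rose in 8 of 21 cases in RPF and fell in 1 (camera adjusted p = 3.4e-04, adjusted p = 0.394 with an estimated correlation), with Tfcp2l1 (2.02), Tbx3 (2.30) and Nr5a2 (1.23). General pluripotency had 1 call, Sox2 (0.71; camera adjusted p = 0.834). Formative genes fell in 4 of 14 (camera adjusted p = 0.0015, adjusted p = 0.316 with an estimated correlation), Dnmt3b (-1.39), Zic2 (-1.69) and Pou3f1 (-1.42) among them. Neuroectoderm genes fell in 3 of 9 (camera adjusted p = 0.0219, adjusted p = 0.316 with an estimated correlation), such as Nes (-2.44) and Pax6 (-1.91). Germline genes rose in 7 of 18 (camera adjusted p = 3.3e-04, adjusted p = 0.408 with an estimated correlation), including Dazl (2.60), Piwil2 (1.75) and Mael (1.67). Imprinted genes fell in 6 (camera adjusted p = 3.4e-04, adjusted p = 0.316 with an estimated correlation), Igf2 (-5.10), Magel2 (-2.98) and Nnat (-2.59) among them. Of 16 p53 targets 5 rose (camera adjusted p = 0.0015, adjusted p = 0.316 with an estimated correlation), including Trp53inp1 (1.23), Cdkn1a (0.85) and Eda2r (1.14). Fibroblast markers counted 1 up and 6 down of 11 (camera adjusted p = 0.0128, adjusted p = 0.394 with an estimated correlation). ERK response genes counted 4 down of 18 (camera adjusted p = 0.0377, adjusted p = 0.394 with an estimated correlation). WNT response genes counted 3 down of 9 (camera adjusted p = 0.0201, adjusted p = 0.316 with an estimated correlation) and retinoic acid response 1 down of 10 (camera adjusted p = 0.0440, adjusted p = 0.316 with an estimated correlation). Without WT replicate 1 no RPF gene was called, so each of these gene calls was lost in that fit. Leaving out 1 culture ended the camera call (adjusted p) of retinoic acid response in RPF (0.0672 without WT replicate 1, 0.135 without WT replicate 2, 0.0508 without Nat1+/- replicate 1 and 0.136 without Nat1+/- replicate 3), ERK response in RPF (0.0733 without WT replicate 2 and 0.193 without Nat1+/- replicate 2) and fibroblast markers in RPF (0.221 without WT replicate 2). Moves of a called median over 1.5 times were those of formative genes in RPF (-0.73 to -1.15 without Nat1+/- replicate 2).

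Ribosomal protein footprints fell in 11 of 81 genes, none rising (median -0.71; camera adjusted p = 1.4e-14, adjusted p = 0.477 with an estimated correlation), with Rpl22l1 (-1.33), Rps27a (-1.04) and Rpl23a (-0.99). Mitochondrially encoded mRNAs were lower as a set (median -1.39; camera adjusted p = 0.0029, adjusted p = 0.477 with an estimated correlation) though none of the 8 passed singly. Of 29 eIF1, eIF2, eIF3 and eIF5 factors 1 fell, Eif1 (-0.76; camera adjusted p = 0.0094, adjusted p = 0.518 with an estimated correlation). Of 60 histones 1 fell (camera adjusted p = 0.0201, adjusted p = 0.684 with an estimated correlation). Without WT replicate 1 no RPF gene was called, and the adjusted p of Eif1 was then 0.332. The lists not called as sets in RPF were those of the cap-binding complex (0 up, 1 down), RAS and MAPK cascade (1 up, 0 down), ATF4 response (0 up, 5 down) and Nat1-dependent mRNAs (1 up, 0 down). Nor were the respiratory chain (4 up, 2 down), trophoblast (0 up, 2 down), mesendoderm (0 up, 1 down), endoderm (2 up, 1 down) and Y-linked genes (0 up, 0 down). In total RNA 12 lists were called as sets by camera (median log2 change; adjusted p), and 0 with an estimated correlation (lowest adjusted p = 0.410 with an estimated correlation). Medians above 0 belonged to naive pluripotency (0.37; 0.0024), cytosolic ribosomal proteins (0.19; 5.2e-04), nuclear-encoded respiratory chain (0.19; 4.1e-04), p53 targets (0.39; 0.0133), germline genes (1.20; 1.1e-04) and replication-dependent histones (0.23; 0.0035). Medians below 0 belonged to formative and primed epiblast (-0.96; 9.6e-05), neuroectoderm (-0.87; 0.0473), ERK response (-0.50; 0.0026), WNT response (-0.96; 0.0016), mitochondrially encoded mRNAs (-1.43; 0.0035) and imprinted genes (-0.95; 2.1e-04). No gene passed for TE with limma (0 of 12933; 663 at a raw p under 0.05), with the culture term or with edgeR, and DESeq2 called 13. The smallest p values belonged to Dgcr2 (1.59), Klf3 (1.54) and Zfp385a (1.65) upward and Rpl22l1 (-1.27), D10Wsu102e (-1.32) and Rbm25 (-0.82) downward, none called. As sets, ribosomal proteins (median -0.90; camera adjusted p = 3.1e-60, adjusted p = 0.347 with an estimated correlation) and the respiratory chain (camera adjusted p = 1.0e-08, adjusted p = 0.432 with an estimated correlation) had lower TE in Nat1+/-. So had histones (camera adjusted p = 2.5e-13, adjusted p = 0.432 with an estimated correlation) and eIF1, eIF2, eIF3 and eIF5 factors (camera adjusted p = 5.4e-07, adjusted p = 0.432 with an estimated correlation). The RAS and MAPK cascade had higher TE (camera adjusted p = 0.0071, adjusted p = 0.347 with an estimated correlation). The naive and ERK response lists were called only with the culture term (camera adjusted p = 0.0260 and 0.0085). The camera call was lost (adjusted p) by histones in RPF (0.718 without WT replicate 1), naive pluripotency in total RNA (0.0733 without WT replicate 1) and ribosomal proteins in total RNA (0.0919 without WT replicate 1). No longer called as sets with 1 culture left out (adjusted p) were respiratory chain in total RNA (0.116 without WT replicate 1), mitochondrially encoded mRNAs in total RNA (0.0643 without WT replicate 1) and histones in total RNA (0.705 without WT replicate 1). Set calls lost with 1 culture left out (adjusted p) were those of neuroectoderm in total RNA (0.0568 without WT replicate 2 and 0.0665 without Nat1+/- replicate 3), RAS and MAPK cascade in TE (0.0724 without WT replicate 1) and respiratory chain in TE (0.273 without WT replicate 1). Leaving out 1 culture ended the camera call (adjusted p) of histones in TE (0.342 without WT replicate 1). With 1 culture left out camera also called trophoblast in RPF (without WT replicate 1 or Nat1+/- replicate 2), ATF4 response in RPF (without Nat1+/- replicate 1) and trophoblast in total RNA (without WT replicate 1 or Nat1+/- replicate 1 or 2). Also uncalled in the main fit but called by camera with 1 culture left out were ATF4 response in total RNA (without WT replicate 1 or Nat1+/- replicate 1), fibroblast markers in total RNA (without WT replicate 1 or Nat1+/- replicate 1 or 2) and mesendoderm in total RNA (without Nat1+/- replicate 2). A called median moved over 1.5 times for mitochondrially encoded mRNAs in RPF (-1.39 to -0.87 without WT replicate 1), histones in RPF (-0.25 to -0.49 without WT replicate 2) and ribosomal proteins in total RNA (0.19 to 0.30 without WT replicate 2). Over 1.5 times was also the move of the called median for respiratory chain in total RNA (0.19 to 0.33 without WT replicate 2), histones in total RNA (0.23 to 0.35 without WT replicate 2) and eIF1, eIF2, eIF3 and eIF5 factors in TE (-0.29 to -0.18 without WT replicate 1). The called median changed over 1.5 times for respiratory chain in TE (-0.22 to -0.42 without WT replicate 2) and histones in TE (-0.49 to -0.86 without WT replicate 2). Values of WTex2 lay among or beside those of A7, B4 and C1 for histones (TE -0.24 against -0.37, -0.23 and -0.31; total RNA 0.26 against 0.29, 0.24 and 0.30). The histone TE of WTex1 was 0.58. Mitochondrially encoded mRNAs had RPF deviations of 1.35 and 0.47 in WT and -1.26, 0.49 and -0.42 in A7, B4 and C1, B4 thus lying beside WTex2. Respiratory chain TE deviations were 0.24 and -0.09 in WT and -0.17, -0.17 and -0.18 in A7, B4 and C1.

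**Figure D3:**
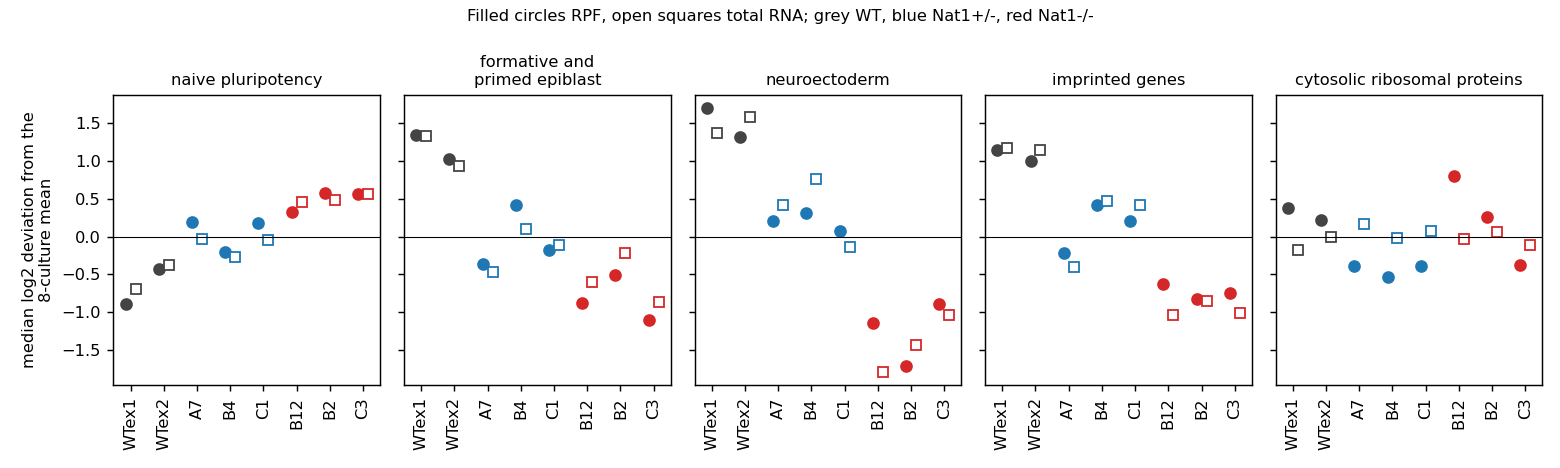
Median log2 deviation of 5 gene lists from the mean of the 8 cultures, one position per culture (grey WT, blue Nat1+/-, red Nat1-/-), for RPF (filled circles) and total RNA (open squares). Ribosomal protein footprints span -0.54 in B4 to 0.80 in B12 while C3 sits at -0.38.

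Whole chromosomes also differed between cultures. Chromosome 8 genes (613 in RPF, 652 in total RNA) had median deviations from the mean of the 8 cultures of -0.25, -0.26 and -0.24 in B12, B2 and C3 for RPF. They were 0.18 and 0.18 in WT and 0.20, 0.08 and 0.18 in A7, B4 and C1. Their median Nat1-/- minus Nat1+/- change was -0.38 in RPF and -0.38 in total RNA. None of 10000 random gene lists of the same size and matched mean expression had a median as low in either assay (lowest -0.01 and -0.02). Such lists of scattered genes do not carry variation shared along a chromosome. The median of chromosome 1 (-0.15 in both assays) also lay below these values, so the random lists do not single out chromosome 8. Chromosome 11 genes were higher in both WT cultures (RPF medians 0.26 and 0.27) and chromosome 1 genes were highest in B4 (0.37).

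**Figure D4:**
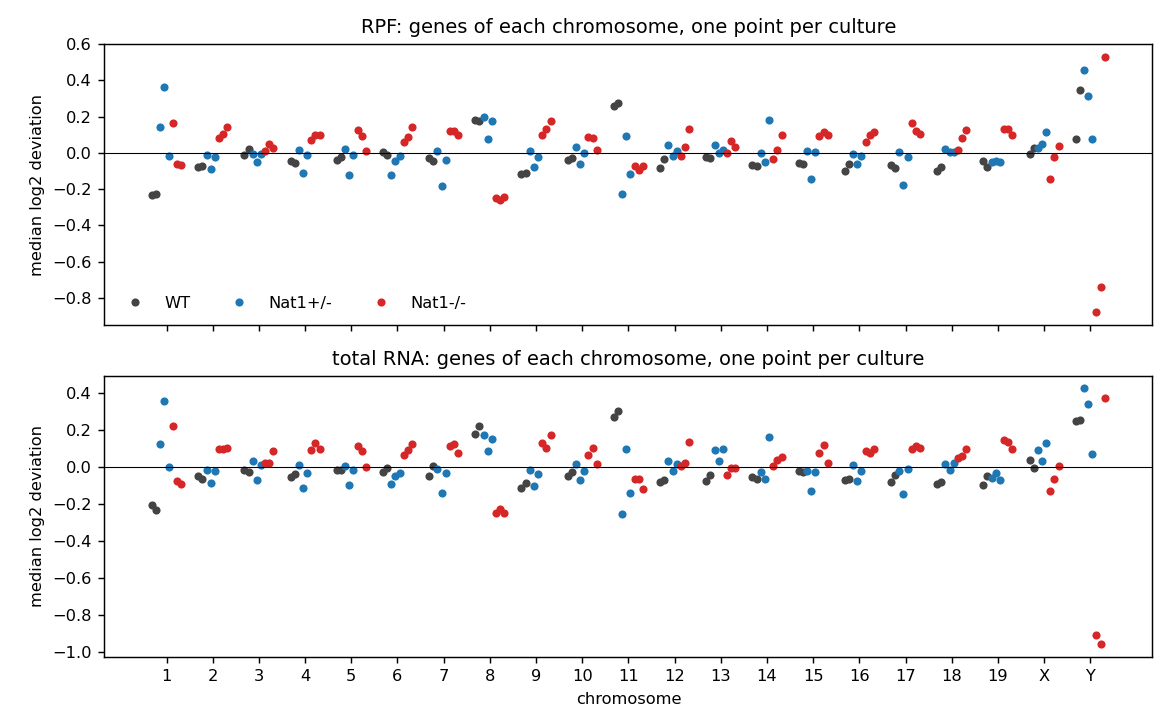
Median log2 deviation of the genes of each chromosome from the mean of the 8 cultures, one point per culture, for RPF (top) and total RNA (bottom). The 3 Nat1-/- cultures sit between -0.23 and -0.26 on chromosome 8 and the other 5 above 0 in both assays.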

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

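The thinned, chromosome-centred and depth-class alternatives and the leave-outs for gene lists were chosen after the data were seen; the others were planned. Of 183 alternative counts of called genes, 133 stayed within 1.5 times of the reported count, including in each comparison those with both filters, both pseudocounts, recomputed factors, robust variance and thinned reads. The Nat1-/- percentage of Nat1+/- stayed under 100 in all 18 alternatives (Eif4g2 level, RPF, 11.7 to 14.0; Eif4g2 level, total RNA, 54.6 to 82.8). Of 18988 values of named genes, 17596 kept direction and side of the threshold, 1013 lost a call and 289 gained one.

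Leaving out 1 culture gave 2821 to 5464 RPF and 3608 to 6261 total RNA calls between Nat1-/- and Nat1+/-. It gave 1866 to 5122 and 2360 to 5216 between Nat1-/- and WT, and 0 to 1207 and 0 to 1059 between Nat1+/- and WT. For TE it gave 6 to 376, 0 to 5 and 0 to 0 (raw p under 0.05 for 123 to 617 genes). Between Nat1+/- and WT, RPF and total RNA counts were 481 and 549 without the variance trend, 2650 and 2769 with the 2 genotypes fitted alone and 2519 and 2559 with DESeq2. TE calls between Nat1-/- and Nat1+/- were 128 with equal sums, 28 without the trend, 28 with the 2 genotypes alone, 387 with DESeq2, 7 against WT and Nat1+/- together, 120 with chromosome-centred values and 6 in shallow cultures. Against WT, TE calls of Nat1-/- were 0 without the trend (360 at a raw p under 0.05), 0 with the 2 genotypes alone (287), 0 with edgeR (326), 0 in deep cultures (584), 39 with DESeq2 and 8 with chromosome-centred values. For Nat1+/- against WT they were 2 with the 2 genotypes alone and 13 with DESeq2. Fewer cultures enter the leave-out, depth-class and 2-genotype fits; for the rest the cause was not tested.

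The replicate block by number paired nothing shown by the data (same-numbered cultures correlated at r = -0.133 to 0.278 in RPF and -0.191 to 0.338 in total RNA, 1 of 7 best matched). It left 162 RPF and 190 total RNA calls between Nat1+/- and WT. The culture block for TE gave 1275, 14 and 0 calls in the 3 comparisons. With an estimated correlation 0 lists were called in any comparison. With fry, which asks whether a list moves at all, list counts went from 8 to 14 (RPF, Nat1-/- against WT), 14 to 9 (RPF) and 12 to 2 (total RNA, both Nat1+/- against WT). For TE they went from 6 to 2, 2 to 1 and 5 to 0. The culture block took the TE lists of Nat1-/- against WT from 2 to 0. Leaving out 1 culture gave 4 to 10, 8 to 11 and 11 to 14 called lists in RPF, 5 to 9, 6 to 10 and 10 to 15 in total RNA and 5 to 6, 3 to 7 and 2 to 5 in TE, comparisons in the order above; a WT culture left alone is assumed to vary like the other groups. For Nat1-/- against WT such fits reversed directions of ribosomal proteins in RPF (adjusted p = 0.0018 to 0.879) and TE (3.3e-20 to 0.335), the respiratory chain in TE (4.8e-11 to 0.916) and histones in TE (5.5e-15 to 0.0566). Directions reversed for Vim RPF between Nat1-/- and Nat1+/- when WT joined the controls (-0.0139, adjusted p = 0.9809). They reversed for Ddx3y total RNA (0.34, adjusted p = 0.0486) and for the Y-linked list in TE (adjusted p = 0.0443), the latter pair with chromosome-centred values, which remove the deviation of the Y-linked genes themselves. With equal sums 6 list medians near 0 flipped. They were total RNA of ribosomal proteins for Nat1-/- against WT (0.05 to -0.07) and TE of Nat1-dependent mRNAs for Nat1-/- against Nat1+/- (0.04 to -0.02). For Nat1+/- against WT they were RPF of the RAS and MAPK cascade (0.0023 to -0.0201), total RNA of eIF1, eIF2, eIF3 and eIF5 factors (0.04 to -0.05) and TE of the trophoblast (-0.02 to 0.05) and ATF4 (-0.05 to 0.02) lists.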

Other observations

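Tests chosen after the result was seen were those of a few changed genes on chromosome 8, both on lower TE, and all 3 on ribosomal protein footprints; the others were written beforehand, though chromosome medians had been seen before the test by stretches of chromosome 8.

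Genes with lower TE beyond the named rule, listed after their values were seen, included chromatin regulators and kinases: Ep300 (-1.09) and Kmt2d (-1.53) beside Crebbp. Others were the WNT pathway genes Gsk3b (-0.94), Gsk3a (-0.96) and Axin1 (-0.91), the PI3 kinase subunit Pik3ca (-1.34), Smad4 (-0.88), Smurf2 (-0.85) and the RNA-binding proteins Mex3a (-1.26), Mex3c (-1.14) and Mex3d (-1.04). All are log2 TE changes of called genes between Nat1-/- and Nat1+/-. Footprints read -0.004 for Gsk3a, -0.11 for Gsk3b, 0.22 for Axin1, -0.15 for Smad4, -0.12 for Ep300 and -0.11 for Mex3a. Total RNA of these rose by 0.73 to 1.16, so their lower TE came mainly from more RNA. Footprints were lower for Pik3ca (-0.98), Mex3c (-0.95), Mex3d (-1.02), Crebbp (-0.82), Smurf2 (-0.66) and Kmt2d (-0.43). No enrichment of these groups was tested.

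Other groupings of the cultures were fitted in the same way. For 3 against 3 cultures only 10 splits exist, too few for a share under 0.05. The genotype split gave 4737 RPF, 5519 total RNA, 75 TE and 1275 culture-blocked TE calls, and the highest of the other 9 gave 0, 0, 0 and 0. In each case 1 of the 10 splits reached the real count. Lists were different. The real split called 6 in RPF, 7 in total RNA and 6 in TE, and other splits up to 12, 9 and 6. Of the 10 splits 6, 5 and 5 called as many, the real one included. The number of list calls therefore does not set genotype apart from other groupings of the cultures. Only these counts, not the lists themselves, were compared between splits. With Nat1-/- set against the other 5 cultures, 1 of 56 splits reached 3841 RPF calls (highest other 277). Likewise 1 of 56 reached 4497 total RNA calls (highest other 120) and 1 of 56 reached 7 TE calls (highest other 0). That is the smallest share these splits allow, and it does not exclude a chance division. Every other split, here and for 3 against 3, joins Nat1-/- cultures with other cultures. Their difference then widens the spread within groups, so few calls were expected. The splits also cannot tell genotype from other features shared by the Nat1-/- cultures, such as the lower chromosome 8 genes. The highest other split in both assays joined WTex1, WTex2 and B4. For TE with the culture block, 2 of 56 splits reached the real 233. With that block the split of the 3 Nat1+/- cultures from the rest called 472, which points to a structure of the cultures that sets Nat1+/- apart in the blocked fit; without the block that split called 0.

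The first pattern is the lower TE of 71 genes in Nat1-/- in the main fit, which does not pair libraries by culture. Because these genes were chosen on the same cultures, 1 Nat1-/- and 1 Nat1+/- culture were held out in turn and the 71 lower genes with the smallest p in the remaining cultures were measured in the held-out pair. In the 6 pairs with shallow total RNA in both cultures their median TE difference was -1.19 to -0.82, so the depth classes of total RNA do not account for the pattern. Over all 9 pairs the median RPF difference was -0.61 to -0.20 (mean -0.43, SD 0.14), below that of all genes in each. The pairs reuse the same Nat1-/- and Nat1+/- cultures, so they are not independent values. A first bound of -0.3 in every pair was missed by 2 pairs with B4 (-0.29 and -0.20), and the bound was changed after that was seen. A rise of RNA without a loss of footprints forbids any shared loss. It was, however, not rejected by a bound set beforehand. Against WT the median TE change of the 71 was -0.74 (70 of 71 negative) and that of Nat1+/- against WT 0.40. The 71 were chosen on these same Nat1-/- and Nat1+/- cultures, which pushes both values this way, so they are not independent support. Whether loss of Nat1 lowers translation of these mRNAs stays open.

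The second pattern is the lower level of chromosome 8 genes in the 3 Nat1-/- cultures. A few strongly changed genes cannot carry it, as at least 71.1% of the chromosome's genes lay below 0 in each Nat1-/- culture and assay. With the chromosome divided in map order into 4 equal stretches, each was lower in each of those cultures, the highest median being -0.10 and the lowest -0.36, which is consistent with a difference in copy number of the whole chromosome; the highest value (-0.1046) barely passed the bound set for it. An extra copy in the WT and Nat1+/- cultures, or its loss in Nat1-/-, could both give this, and neither DNA content nor an effect of genotype was tested. Removing chromosome medians kept 60 of 68 list calls and gave 120 TE calls.

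The third pattern is the low level of ribosomal protein footprints in Nat1+/-. Poor recovery of short mRNAs stays open, since the respiratory chain showed 0.366 and the histones, also short, 0.644 of the ribosomal protein TE change, and mRNA length was not tested. Total RNA libraries do not enter the RPF values, so their depth cannot lower the footprints themselves. The list median of Nat1+/- against WT was -0.71 in RPF and 0.19 in total RNA. For the TE difference of these genes the depth classes of total RNA stay open. The lowest shallow Nat1-/- culture in TE (C3, -0.23) lay above the highest Nat1+/- culture (-0.47) by less than it lay below the other shallow one (B2, 0.22). RPF library depth remains a candidate source, because the 4 deepest RPF libraries were the 4 with the highest ribosomal protein footprints (4 of 4, met by 1.43% of random choices). Across the 8 cultures, however, depth and the list median were not clearly related (Pearson r = 0.569, permutation p = 0.157, Spearman rho = 0.619, permutation p = 0.114, and r = 0.591 without the 2 cultures of most extreme depth). With every library thinned to 13206434 reads, 63 of the 68 list calls over all lists and comparisons held and 0 reversed. Read number alone therefore accounts for few list calls, while features of a library that go with depth stay open. The 4 cultures with the deepest RPF libraries also had positive scores on the second component of total RNA. A feature that goes with depth and another shared feature of those cultures thus stay open, and genotype is untested beyond its exact permutation p of 0.1.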
